A study of Homo sapiens with 8 samples.

How the data were processed

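RNA was measured on 8 Affymetrix expression arrays that carry 54675 probe sets each. The cells were human embryonic stem cells of the H9 line per the labels, an established line, grown by a standard protocol in mTeSR medium. They were undifferentiated or had formed embryoid bodies, which are floating aggregates in which pluripotent cells differentiate. Cells of both stages received 0 or 20 mM ethanol for 24 h, with 2 arrays in each of the 4 groups. The labels call these arrays duplicates and do not say whether they came from separate cultures, so every p-value measures the spread between these samples only. A paired reading of the replicate letters had no basis in the values, because the deviations of like-lettered arrays from their group means correlated by only -0.026 to 0.049 across genes.

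The deposited values are log10 array signals, by the evidence of the values themselves. They ran from -1.46 to 4.61, and the mean of the signals after trimming 2% of probe sets at each end was 500 to 500.1 on every array, the form of globally scaled MAS 5 signals. The labels name RMA as the authors' processing, without a version, but RMA gives neither negative values of this size nor a shared trimmed mean. The plan written before the data were examined assumed RMA values on the log2 scale. The deposited log10 values were therefore converted to log2 by a constant factor, and no further normalisation was applied. Per array, the median signal was 69.2 to 102. With 2 arrays per group, the number of arrays limits the precision.

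Probe sets were named from a platform annotation: 41097 named 1 gene, 1801 named several genes, 11777 named none, and 62 were controls. Each of the 19775 genes with a probe set of its own was represented by the probe set with the highest mean over the 8 arrays. A gene was tested when at least 2 arrays lay above that array's median, which left 14079 genes. With 2 arrays per group, a dim gene could enter through 1 group alone, which favours a higher value in that group. Log2 fold changes came from limma 3.58.1 in R 4.3.3, with 1 mean per group fitted to all 8 arrays, 4 residual and 1.81 prior degrees of freedom, and no intensity trend in the variance. The 6 contrasts were ethanol in undifferentiated cells, ethanol in embryoid bodies, the difference between these effects, their average, and embryoid bodies against undifferentiated cells at 0 mM and at 20 mM. Benjamini-Hochberg adjusted p under 0.05 counted as a call, and errors are standard errors of the fitted log2 change unless named otherwise.

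Before the data were examined, 51 gene lists were fixed, for pluripotency, germ layers and cell types, signalling, metabolism, stress responses, chromatin and RNA quality. They hold 1140 genes, of which 1019 had a probe set of their own and 887 were tested. The 50 lists with at least 5 tested members were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, and adjusted over the lists. Each call was repeated with an estimated correlation and with fry, which asks whether a list's genes move, on balance, in one direction. The estimated correlation, with 4 residual degrees of freedom behind it, called no list in any of the 6 contrasts. A call lost under it therefore does not tell one list from another. Member genes were adjusted over all genes and also over the list alone. For each list, the median was also placed among 10000 random lists matched on mean expression.

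Named genes follow a rule fixed beforehand. In each contrast they are the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups, without the overlap condition for the difference and the average. Where no gene was called, they are the 5 smallest p-values in each direction. Up to 4 members with the smallest p are named per list described, and 11 genes of pluripotency, DNA methylation and ethanol breakdown were always to be reported for ethanol. Genes used to check the arrays against the named cell line were tested with the rest but are not named.

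The fit was tested on simulated data. With 50 genes at each size among 14079, 63.8% of genes changed by a log2 value of 1 and 23.4% of those changed by 0.5 were recovered, and 5.75% of all calls were false. With a trended and robust variance 69.6% and 34.6% were recovered, and 4.01% of calls were false. Lists shifted by a log2 value of 1 were recovered in 100% of cases, with 0.15 other lists called per run. The simulated noise was independent between genes and held no intensity trend, so these rates need not hold for lists on the real arrays. The shift of 1 was also larger than the ethanol medians of the lists called in embryoid bodies, at most 0.95 for HOX.

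Alternatives tried were no filter, a filter at the 75th percentile, the mean of a gene's probe sets, leaving out probe sets of the _x_at and _s_at kinds, the probe set with the highest SD, quantile normalisation, median centring, a trended and robust variance, a replicate block, array weights, a looser or a fold-change threshold, only the 4 arrays compared, and leaving out each array in turn. A cyclic loess normalisation was added after seeing the data. Figures were drawn in Python 3.11.15. No genome build was used, so positions are not given, and probe sets that name several genes were left out of the tests.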

Results

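The series asked how 24 h of 20 mM ethanol changed gene expression in human embryonic stem cells, before and after differentiation into embryoid bodies. Expression arrays measured total RNA of cells that the labels name as the H9 line, in 4 groups of 2 arrays: undifferentiated cells and embryoid bodies, each with 0 or 20 mM ethanol. Median signals were 69.2 to 79.4 in the undifferentiated arrays, 83.2 to 85.1 in embryoid bodies without ethanol and 102 in both embryoid body arrays with ethanol, against a common trimmed mean of 500 to 500.1. Stage separated the arrays along the first principal component, which held 80.5% of the variance, against 5.13% for the next. Replicate arrays correlated at 0.981 to 0.988, arrays of the same stage and different dose at 0.978 to 0.984, and arrays of different stages at 0.872 to 0.894. In undifferentiated cells replicates were at 0.9843 and 0.9806 and pairs of different dose at 0.9807 to 0.9841, so these correlations did not separate the doses. In embryoid bodies replicates were at 0.988 and 0.9868, above the pairs of different dose at 0.9784 to 0.9815. Ratios of 3′ to 5′ signal were 1.35 to 1.58 for ACTB and 0.851 to 0.977 for GAPDH. In a check of transcripts that differ between cell lines, 4 of the 8 arrays did not match the line named in their labels, and all 4 belonged to 1 of the 2 stages.

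With ethanol, 6 genes rose and 4 fell in embryoid bodies, among 14079 tested. AHSG, which encodes the liver plasma protein fetuin-A, rose 3.05-fold (log2 change 1.61 ± 0.07, n = 2 arrays per group, adjusted p = 0.00956). The homeobox gene LHX8 rose 2.69-fold (adjusted p = 0.049), the mitochondrial stress relay DELE1 2.29-fold (adjusted p = 0.044), the interstitial collagenase MMP1 2.26-fold (adjusted p = 0.0468), the noncoding transcript DNM3OS 2.14-fold (adjusted p = 0.044) and the transporter ABCC10 1.91-fold (adjusted p = 0.044). The caudal-type homeobox gene CDX4 fell 5.62-fold (log2 change -2.49 ± 0.22, adjusted p = 0.049). The noncoding transcripts LINC02525 and LINC01315 fell 12.2-fold (adjusted p = 0.044) and 1.88-fold (adjusted p = 0.049), and the chemokine CCL26 fell 1.78-fold (adjusted p = 0.049). With ethanol, the signals of CDX4 (13.2), LINC02525 (7.24) and CCL26 (51.9) lay under the array median. Without it, CDX4 (74.1) was also under the array medians of 83.2 and 85.1, and LINC02525 (88.1) and CCL26 (92.3) were close to them, so these folds are imprecise. Among probe sets of DELE1 outside the _x_at and _s_at kinds, the change was -0.15.

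**Figure D1:**
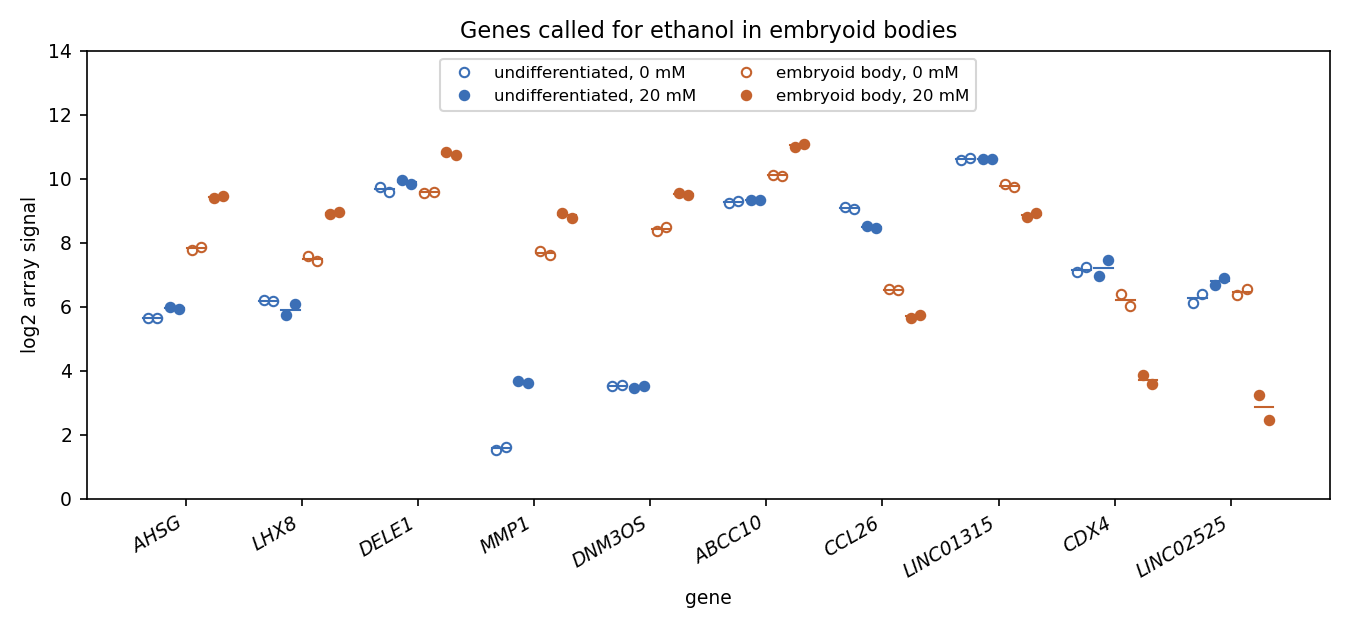
The log2 array signal (vertical axis) of the 10 genes called for ethanol in embryoid bodies (horizontal axis) is shown for each of the 8 arrays, open circles at 0 mM and filled circles at 20 mM, with lines at the group means of 2 arrays. In embryoid bodies both ethanol arrays lie beyond both control arrays for each gene, and AHSG moves from a mean signal of 226 to 692.

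The calls in embryoid bodies rested on few arrays. An unadjusted p under 0.05 was found for 3137 genes, against 704 by chance. Median centring gave 6327, so a shift of whole arrays can also raise this number. The count fell from 10 to 0 without any of the undifferentiated arrays, which contribute to the shared variance only, to 2 without the 0 mM embryoid body replicate A, 4 without its replicate B, 2 without the 20 mM replicate A and 1 without its replicate B. Each of the 10 genes passed under 5 to 11 of 21 or 22 alternatives. The count was 0 with a replicate block, 0 with only the 4 embryoid body arrays in the fit, 959 with a trended and robust variance and 473 with the stricter filter. Median centring moved the median ethanol change of all genes by -0.28 in embryoid bodies and gave 162 genes higher and 4071 lower.

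Genes of mesenchyme and its extracellular matrix were higher as a group with ethanol in embryoid bodies. The median log2 change of the 24 tested members was 0.33, 18 were positive, and camera gave adjusted p = 0.00137 (adjusted p = 0.528 with an estimated correlation). No member passed over all genes, and 9 rose adjusted over the list alone. Values were 1.86-fold for the matrix protein POSTN (log2 change 0.90 ± 0.14), 1.93-fold for the proteoglycan LUM, 1.45-fold for the collagen gene COL5A1 and 1.36-fold for COL6A2. Expression-matched random lists had a median of -0.06, and the list lay at the 100th percentile of them.

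Markers of endoderm and yolk sac, of mesoderm and the HOX genes were also higher as groups in embryoid bodies with ethanol. The 18 endoderm and yolk sac genes had a median of 0.58, with 16 positive (adjusted p = 0.0191; adjusted p = 0.528 with an estimated correlation), and included the fetal plasma protein AFP at 1.58-fold, the fibrinogen chain FGB at 2.14-fold and CDH17 at 2.45-fold. The 14 mesoderm genes had a median of 0.34, with 12 positive (adjusted p = 0.0343; 0.504 as the adjusted p with an estimated correlation), and included the transcription factors HAND1 at 1.57-fold and TWIST1 at 1.66-fold and the receptor PDGFRA at 1.51-fold. The 10 HOX genes, which pattern the body axis, had a median of 0.95, with 9 positive (adjusted p = 0.0191; adjusted p = 0.504 with an estimated correlation). HOXB3 was 1.78-fold and HOXC4 2.29-fold higher, from signals of 195 and 62.4, and HOXC4 and CDH17 started under the array median. HOXC5 (30.9), HOXC6 (66.1) and HOXC11 (40.3) also started under it. HOXC6 lay above the array median only in embryoid bodies with ethanol (207). The filter therefore kept HOXC6 through that group alone, which favours a rise. No member of these lists passed over all genes. Adjusted over the list alone, 1 endoderm and yolk sac gene, 4 mesoderm genes and 3 HOX genes rose. Cyclic loess ended the calls of all 3 lists, with medians of 0.52, 0.34 and 0.66, and quantile normalisation ended that of HOX. Leaving out the 20 mM embryoid body replicate B also ended all 3, and 6 of the 10 lists called in embryoid bodies were then called. The endoderm call also ended without the 0 mM embryoid body replicate B, with 8 lists called. The mesoderm call also ended without either 20 mM undifferentiated array (8 lists each), the 0 mM embryoid body replicate A (7) or the 20 mM replicate A (9). By fry, 12 lists were called, the endoderm list not among them.

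Core pluripotency genes were lower as a group in embryoid bodies with ethanol. The median of the 20 tested members was -0.17, 17 were negative, and camera gave adjusted p = 0.00137 (adjusted p = 0.504 with an estimated correlation). No member passed over all genes, and 6 fell adjusted over the list alone. PRDM14, a repressor active in pluripotent and germ cells, was 1.55-fold lower (log2 change -0.63 ± 0.11, adjusted p = 0.0823). USP44 was 1.30-fold, NANOG 1.24-fold and VRTN 1.27-fold lower. Cyclic loess ended the call, with a median of -0.06.

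**Figure D2:**
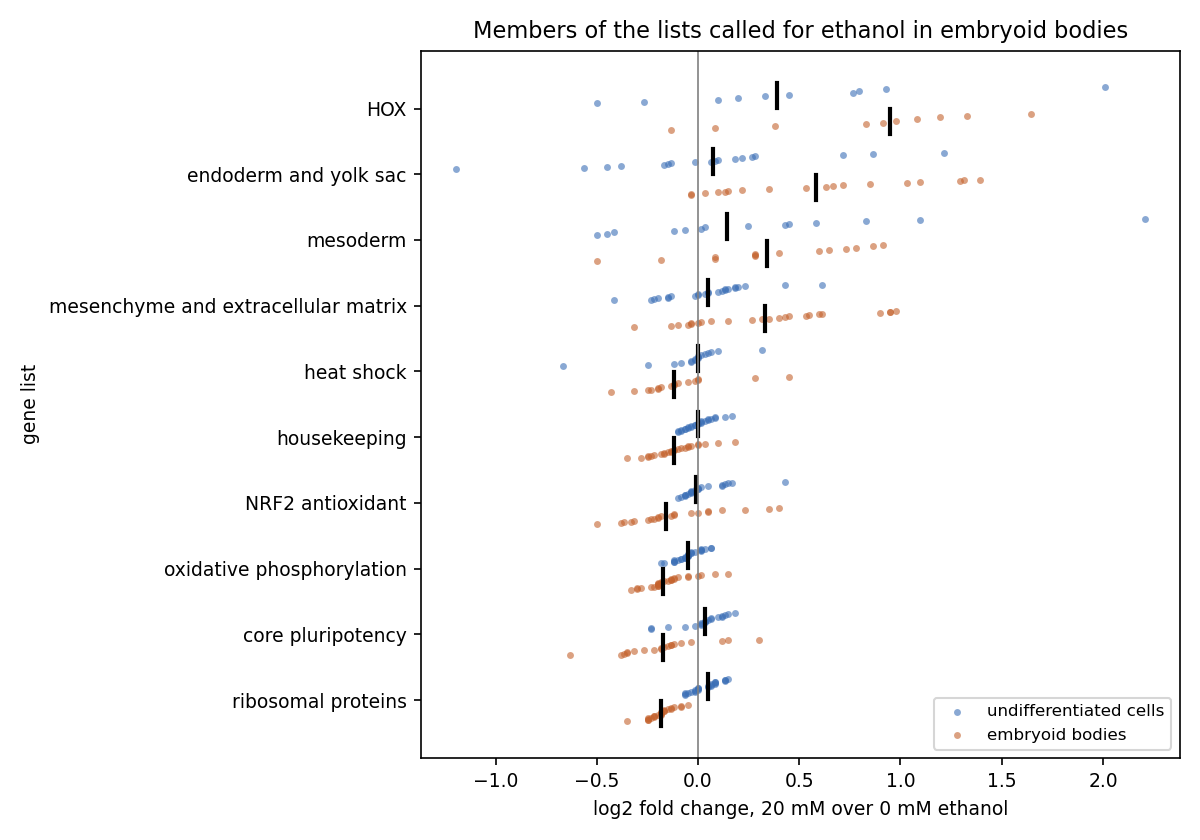
Each point is a tested member of a gene list (vertical axis) at its log2 fold change between 20 and 0 mM ethanol (horizontal axis), in undifferentiated cells or embryoid bodies, and black bars are list medians. The 10 lists are those called in embryoid bodies, where the HOX median is 0.95 and the ribosomal protein median -0.18; cyclic loess turns the housekeeping median from -0.12 to 0.02 and keeps the sign of the others.

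Lists of abundant transcripts were slightly lower in embryoid bodies with ethanol. All 25 tested ribosomal protein genes had negative values, with a median of -0.18 (adjusted p = 3.92e-05; adjusted p = 0.608 with an estimated correlation), among them RPL18 at -0.35 and RPS9 at -0.25. Of 28 oxidative phosphorylation genes, 24 were negative, with a median of -0.17 (adjusted p = 0.000117; adjusted p = 0.528 with an estimated correlation), among them COX4I1 at -0.33 and SDHC at -0.30. The 22 NRF2 antioxidant genes had a median of -0.16 (adjusted p = 0.017; adjusted p = 0.504 with an estimated correlation), and the pentose phosphate enzymes TKT at -0.50 and TALDO1 at -0.38 lay lowest by p. The 17 heat shock genes had a median of -0.12 (adjusted p = 0.0463; adjusted p = 0.504 with an estimated correlation), with HSPB1 at -0.43 and CHORDC1 at 0.28. The 25 housekeeping genes had a median of -0.12 (camera adjusted p = 0.00719, and adjusted p = 0.528 with an estimated correlation), or 0.02 after cyclic loess. In these 5 lists no member passed over all genes, and adjusted over the list alone 2 NRF2 genes fell. Quantile normalisation and cyclic loess each ended all 5 calls, and leaving out probe sets of the _x_at and _s_at kinds left 2 of the 10 lists called. The heat shock call ended without any of the 8 arrays, which left 6 to 9 lists, and the NRF2 call without the 0 mM embryoid body replicate A, which left 7. Ribosomal protein and housekeeping genes were not called by fry.

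Fold changes in embryoid bodies followed mean expression. Median log2 changes with ethanol ran from 0.33 in the dimmest decile of tested genes to -0.10 in the brightest. In undifferentiated cells they ran from 0.13 to -0.02. The cardiac and smooth muscle list, at a median of -0.13 (adjusted p = 0.176), and the neuron list, at -0.03 (adjusted p = 0.824), were not higher in embryoid bodies with ethanol.

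**Figure D3:**
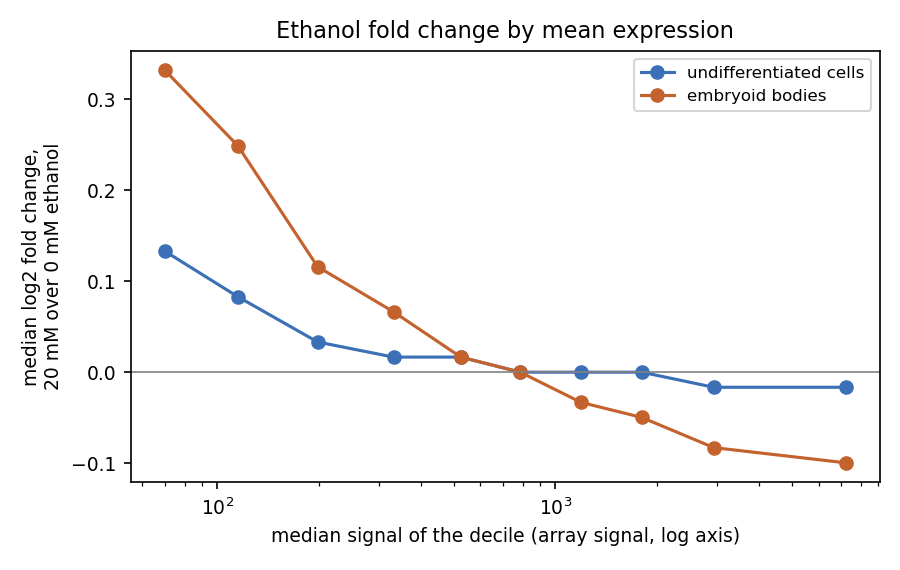
The median log2 fold change between 20 and 0 mM ethanol (vertical axis) is drawn for each decile of tested genes by mean expression, at the median array signal of that decile (horizontal log axis), for both stages. In embryoid bodies it falls from 0.33 at a signal of 70 to -0.10 at 7220.

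In undifferentiated cells, MMP1 was the called gene. It was called higher (n = 2 arrays per group, adjusted p = 0.0112) at signals of 2.99 and 12.6, both far under the array medians, so no fold is given. No other gene passed, although 986 had an unadjusted p under 0.05, against 704 by chance and 1722 after median centring. The MMP1 call ended when any embryoid body array was left out, with 0 genes called, with a trended and robust variance, with a replicate block, and with only the 4 undifferentiated arrays in the fit, and it held under 14 of 21 alternatives. Median centring moved the median of all genes by -0.13. Leaving out an undifferentiated array kept MMP1 and raised the count to 27 and 24 without the 0 mM replicates A and B, and to 8 and 34 without the 20 mM replicates A and B.

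None of the 50 lists was called in undifferentiated cells by camera, where 6 had an unadjusted p under 0.05, or by fry. Metallothioneins, which bind zinc and copper, had the smallest adjusted p together with oxidative phosphorylation (adjusted p = 0.0758 for each; adjusted p = 0.908 with an estimated correlation). Of 10 metallothionein genes 8 were negative, with a median of -0.16, and MT2A was 1.14-fold and MT1F 1.23-fold lower. Of 28 oxidative phosphorylation genes 21 were negative, with a median of -0.05, and CYC1 was 1.14-fold lower. Median centring called oxidative phosphorylation lower (median -0.18) among 3 lists, and a trended and robust variance called both lists. The mean of all probe sets and a replicate block each called metallothioneins. No member of either list passed, over all genes or over the list alone. Without the 20 mM undifferentiated replicate B, 8 lists were called. Without the 0 mM replicate B, 5 were called, both of these lists among them. Without the 20 mM replicate A, 1 was called, as was 1 without either of the 0 mM embryoid body arrays.

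Enzymes of ethanol and aldehyde breakdown did not pass as a group. In undifferentiated cells the 14 tested genes had a median of -0.01 (adjusted p = 0.546), with ALDH3A2 at -0.28 ± 0.11. ALDH1A2, at signals of 22.6 and 10.4, was under the array median in both groups. In embryoid bodies the median was -0.08, the mean 0.00 and adjusted p = 0.286, and 2 members fell adjusted over the list alone. ADH5, the class III alcohol dehydrogenase, was at 0.07 ± 0.08 in undifferentiated cells and -0.38 ± 0.08 in embryoid bodies (adjusted p = 0.946 and 0.1). ALDH9A1 was at -0.37 in embryoid bodies (adjusted p = 0.098). The mitochondrial aldehyde dehydrogenase ALDH2 was at 0.07 and -0.02, and catalase (CAT) at 0.25 and 0.13. Median centring turned the undifferentiated values of ADH5 and ALDH2 and the embryoid body value of CAT negative. Quantile normalisation and cyclic loess turned the embryoid body value of ALDH2 positive. CYP2E1 was too dim to be tested.

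Genes of DNA methylation showed no call. In embryoid bodies the 21 tested genes had a median of 0.07 and a camera direction below other genes (adjusted p = 0.919), and the median was negative under quantile normalisation, median centring and cyclic loess. HELLS was at 0.48 ± 0.12 and KDM2B at -0.28 ± 0.06 (adjusted p = 0.119 and 0.105). The methyltransferases DNMT1, DNMT3A and DNMT3B were at 0.18, 0.22 and 0.07 in undifferentiated cells and at 0.12, -0.10 and -0.18 in embryoid bodies, and the demethylating enzyme TET1 at -0.02 and -0.28. Median centring turned DNMT1 in embryoid bodies and DNMT3B in undifferentiated cells negative, and quantile normalisation turned TET1 in undifferentiated cells positive.

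Among pluripotency regulators, NANOG was at 0.03 ± 0.07 in undifferentiated cells (-0.10 when median centred) and -0.32 ± 0.07 in embryoid bodies (adjusted p = 0.975 and 0.0989). SOX2 was at 0.13 ± 0.09 and -0.35 ± 0.09 (adjusted p = 0.858 and 0.125). POU5F1 had no probe set of its own, and a set shared with related sequences had mean signals of 15000 and 14800 in undifferentiated cells and 6920 and 5070 in embryoid bodies, at 0 and 20 mM.

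The ethanol effect on 3 lists differed between the stages. The change in embryoid bodies minus that in undifferentiated cells had a median of -0.25 for ribosomal proteins (adjusted p = 0.000142), -0.20 for core pluripotency (adjusted p = 0.00387) and 0.23 for mesenchyme and extracellular matrix (adjusted p = 0.0102). With an estimated correlation adjusted p = 0.664 for each, and fry called 0. For the pluripotency factor SOX2 the difference was -0.48, for PRDM14 -0.75, for the collagen gene COL3A1 1.36, for LUM 0.81 and for RPS15 -0.33. No member passed over all genes, and 2 core pluripotency genes passed, negative, adjusted over the list alone. The mesenchyme call ended without the 0 mM undifferentiated replicate B and without the 20 mM embryoid body replicate A, each leaving 2 lists. Counts were 7 and 5 without the 20 mM undifferentiated replicates A and B. Cyclic loess and the probe sets with the highest SD ended the ribosomal and pluripotency calls, quantile normalisation the ribosomal call, and leaving out probe sets of the _x_at and _s_at kinds all 3. Median centring moved the median of all genes by -0.15 and gave 9 lists. The 4 arrays that did not match the named line were all of 1 stage, so this difference could not be separated from a difference between lines.

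For single genes the ethanol effect was not called different between the stages by limma, with a smallest adjusted p of 0.122 and 1828 genes at an unadjusted p under 0.05. A trended and robust variance called 31 genes and the stricter filter 13. The smallest p-values in each direction belonged to AHSG (1.30 ± 0.10), the cystatin CST2 (1.71), SNRK-AS1 (1.36), DNM3OS (1.15) and LINC01741 (1.18), and to LINC02525 (-4.14), PPP1R18 (-1.05), CDX4 (-2.56), ZPLD1 (-2.38) and LINC01315 (-0.91). AHSG, DNM3OS, SNRK-AS1 and ZPLD1 lay under the array median in undifferentiated cells, and CDX4 and LINC02525 in embryoid bodies with ethanol. Without the 0 mM undifferentiated replicate A 5 genes passed, and without the 20 mM replicate B 10 did. Across genes, which are not independent replicates, ethanol changes in the stages correlated by 0.15 (Spearman 0.14), and 52% shared their sign. It was 0.084 without a filter, 0.085 with the stricter filter, 0.089 after quantile normalisation and 0.095 after cyclic loess. In other pairings of the same arrays it was -0.041 to 0.059. The ethanol change correlated with the stage difference by 0.11 in undifferentiated cells, against 0.024 and 0.061 for other splits of those arrays, but 0.021 and 0.028 without the 20 mM undifferentiated replicates A and B, 0.18 without the 0 mM replicate B, 0.058 without a filter, 0.20 with the stricter filter and 0.040 after quantile normalisation. In embryoid bodies it was 0.19, against 0.02 and 0.0055 for other splits, with 0.063 without a filter, 0.34 with the stricter filter and 0.13 after cyclic loess. From the dimmest to the brightest decile, median ethanol changes ran from 0.13 to -0.02 in undifferentiated cells and from 0.33 to -0.10 in embryoid bodies. The stage difference at 0 mM ran from 0.18 to -0.22. This shared slope may add to these correlations, and whether the other splits carry it was not tested.

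Averaged over stages, 4 genes rose with ethanol and 1 fell. MMP1 rose 3.09-fold (log2 change 1.63 ± 0.07, n = 4 arrays per dose, adjusted p = 0.00617) and AHSG 1.95-fold (adjusted p = 0.0125). FRMD1 rose 3.11-fold (adjusted p = 0.0248), the hexokinase-like gene HKDC1 2.72-fold (adjusted p = 0.0313), and CCL26 fell 1.63-fold (adjusted p = 0.0313). Signals under the array median make these folds imprecise: MMP1 and AHSG in undifferentiated cells, FRMD1 there at 0 mM, HKDC1 in all groups but embryoid bodies with ethanol, and CCL26 in that group. An unadjusted p under 0.05 was found for 2418 genes. The count was 18 and 11 without the 0 mM undifferentiated replicates A and B, 0 and 18 without the 20 mM ones, 2 without either 0 mM embryoid body array and 0 without either 20 mM one, and 1 with a replicate block. Median centring moved the median of all genes by -0.21 and gave 126 genes higher and 3871 lower.

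Among 50 lists, 9 were called for the averaged effect, 3 higher and 6 lower, and fry called 0. Mesenchyme (median 0.14, adjusted p = 0.0113) and mesoderm (0.29, adjusted p = 0.0348) were higher. Core pluripotency (-0.07, adjusted p = 0.0188), ribosomal protein (-0.07, adjusted p = 0.00922), housekeeping (-0.06, adjusted p = 0.0227) and heat shock genes (-0.09, adjusted p = 0.0348) were lower. With an estimated correlation adjusted p = 0.647 for ribosomal proteins and 0.546 for each of the other 8 lists, so none of the 9 was then called. Oxidative phosphorylation had a median of -0.11 (adjusted p = 2.07e-05; adjusted p = 0.546 with an estimated correlation), with 26 of 28 members negative and CYC1 at -0.19. The 10 metallothionein genes had a median of -0.12 (adjusted p = 0.0496; adjusted p = 0.546 with an estimated correlation), with MT1E at -0.27 and MT1G at -0.20. HOX genes had a median of 0.76 (adjusted p = 0.0188; adjusted p = 0.546 with an estimated correlation), with HOXC11 at 0.89 and HOXB9 at 0.84, the former under the array median in embryoid bodies and the latter in undifferentiated cells at 0 mM. None of the members of the 9 lists passed over all genes, and 2 HOX, 2 mesoderm and 4 mesenchyme genes rose adjusted over the list alone. Quantile normalisation and cyclic loess each ended 8 of the 9 calls and left that of mesenchyme, and median centring ended that of metallothioneins. Leaving out the 0 mM undifferentiated replicate A left 4 lists, the 0 mM embryoid body replicate A 3, and the 20 mM embryoid body replicates A and B 6 and 5, with HOX among them each time.

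Without ethanol, embryoid bodies differed from undifferentiated cells in 7426 of 14079 genes, of which 3948 were higher and 3478 lower. The endodermal noncoding transcript LINC00261 rose 237-fold (log2 change 7.89 ± 0.35, n = 2 arrays per group, adjusted p = 6.6e-05), from a signal of 8.61 to 2040. DEFA6, PRSS2, MGP, FABP1, MUC15, SCN3A, HSD17B2, FGB and GASK1B rose 166- to 75.9-fold, each from an undifferentiated signal under the array median. As for LINC00261, these folds and their ranks are therefore imprecise. The segmentation gene RIPPLY2 fell 28.8-fold (log2 change -4.85 ± 0.63, adjusted p = 0.0018) and the chemokine CXCL5 11.7-fold, from a signal of 5130 to 437. AIF1, RAX2, TCF24, NPTX1, PLA2G4C, NETO1-DT, SLC38A2-AS1 and HMX2 fell 15.1- to 10.4-fold. Among these falls, all but CXCL5 and NPTX1 ended under the array median, where folds are imprecise. At 20 mM RAX2 went the other way, from a signal of 26.9 in undifferentiated cells to 104 in embryoid bodies. NETO1-DT was at 119 and 68.4 at that dose, against 150 and 14.1 without ethanol. A change of at least 2-fold was found for 1603 higher and 645 lower genes. Median centring moved the median of all genes by -0.27 and gave 2558 higher and 5634 lower. Quantile normalisation shifted single genes by a median of -0.15 and took the median of all genes from 0.02 to -0.07. Stage and cell line cannot be told apart in this comparison, given the 4 arrays of 1 stage that did not match the named line.

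Markers of all 3 germ layers were higher in embryoid bodies at 0 mM. In the mesenchyme and extracellular matrix list 23 of 24 genes rose and 1 fell, with a median of 1.67 (adjusted p = 3.85e-09; adjusted p = 0.155 with an estimated correlation), LUM rising 67.6-fold and POSTN 28.5-fold. Of 18 endoderm and yolk sac genes 17 rose, with a median of 4.41 (adjusted p = 1.63e-07; adjusted p = 0.17 with an estimated correlation), such as the apolipoproteins APOA1 at 65.3-fold and APOA2 at 58.9-fold and AFP at 37.2-fold. Of 14 mesoderm genes 12 rose and 1 fell, with a median of 3.31 (adjusted p = 0.000212; adjusted p = 0.155 with an estimated correlation), TWIST1 and PDGFRA rising 18.8- and 18.6-fold, TWIST1 from under the array median. Of 18 neuroectoderm genes 14 rose and 2 fell, with a median of 2.36 (adjusted p = 3.87e-05; adjusted p = 0.155 with an estimated correlation), ZIC1 rising 54.3-fold and PAX6 12.9-fold. Of 13 neural crest genes 10 rose and 2 fell, with a median of 3.11 (adjusted p = 0.00214; adjusted p = 0.155 with an estimated correlation), MSX1 rising 22.6-fold. Of 17 neuron genes 10 rose, or 11 adjusted over the list alone, and 2 fell, with a median of 1.21 (adjusted p = 0.0465; adjusted p = 0.214 with an estimated correlation). MAP2 rose 9.23-fold and RBFOX3 fell 2.69-fold, although its probe set with the highest SD gave 0.23. The neuron call ended without the 0 mM undifferentiated replicate B, the 0 mM embryoid body replicate A or either 20 mM embryoid body array, each leaving 19 lists, and also with the stricter filter.

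Transcript lists of signalling pathways that pattern the embryo, of adhesion molecules and of the unfolded protein response were also higher. Pathway activity was not measured, and the lists include antagonists. Of 21 BMP targets 19 rose (median 2.92, adjusted p = 2.87e-08; adjusted p = 0.155 with an estimated correlation), with the antagonist GREM1 at 22.4-fold. Of 16 Hedgehog genes 13 rose (median 1.80, adjusted p = 4.84e-05; adjusted p = 0.155 with an estimated correlation), HHIP by 61.0-fold and the receptor PTCH1 by 5.75-fold. Of 21 WNT targets 13 rose and 4 fell (median 1.13, adjusted p = 0.00769; adjusted p = 0.155 with an estimated correlation), DKK1 rising 56.9-fold and LGR5 36.3-fold. Of 21 Notch genes 13 rose and 2 fell (median 0.85, adjusted p = 0.00281; adjusted p = 0.155 with an estimated correlation), HEY1 rising 4.79-fold. Of 16 retinoic acid response genes 12 rose and 1 fell (median 1.0, adjusted p = 0.00281; adjusted p = 0.219 with an estimated correlation), NR2F1 rising 71.6-fold. Of 19 genes of L1 family adhesion molecules and cadherins 13 rose and 4 fell (median 2.08, adjusted p = 0.00212; adjusted p = 0.155 with an estimated correlation), CDH6 rising 20.2-fold and NCAM1 4.95-fold. Of 21 unfolded protein response genes 18 rose and 1 fell (median 0.55, adjusted p = 0.000119; adjusted p = 0.162 with an estimated correlation), HSPA5 rising 1.72-fold. Adjusted over the list alone, the counts of these 7 lists were unchanged. Undifferentiated signals of HHIP (21.9), LGR5 (44.2) and NR2F1 (63.8) lay under the array median, so their folds are imprecise. The Notch call ended without probe sets of the _x_at and _s_at kinds and with the probe sets of highest SD.

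**Figure D4:**
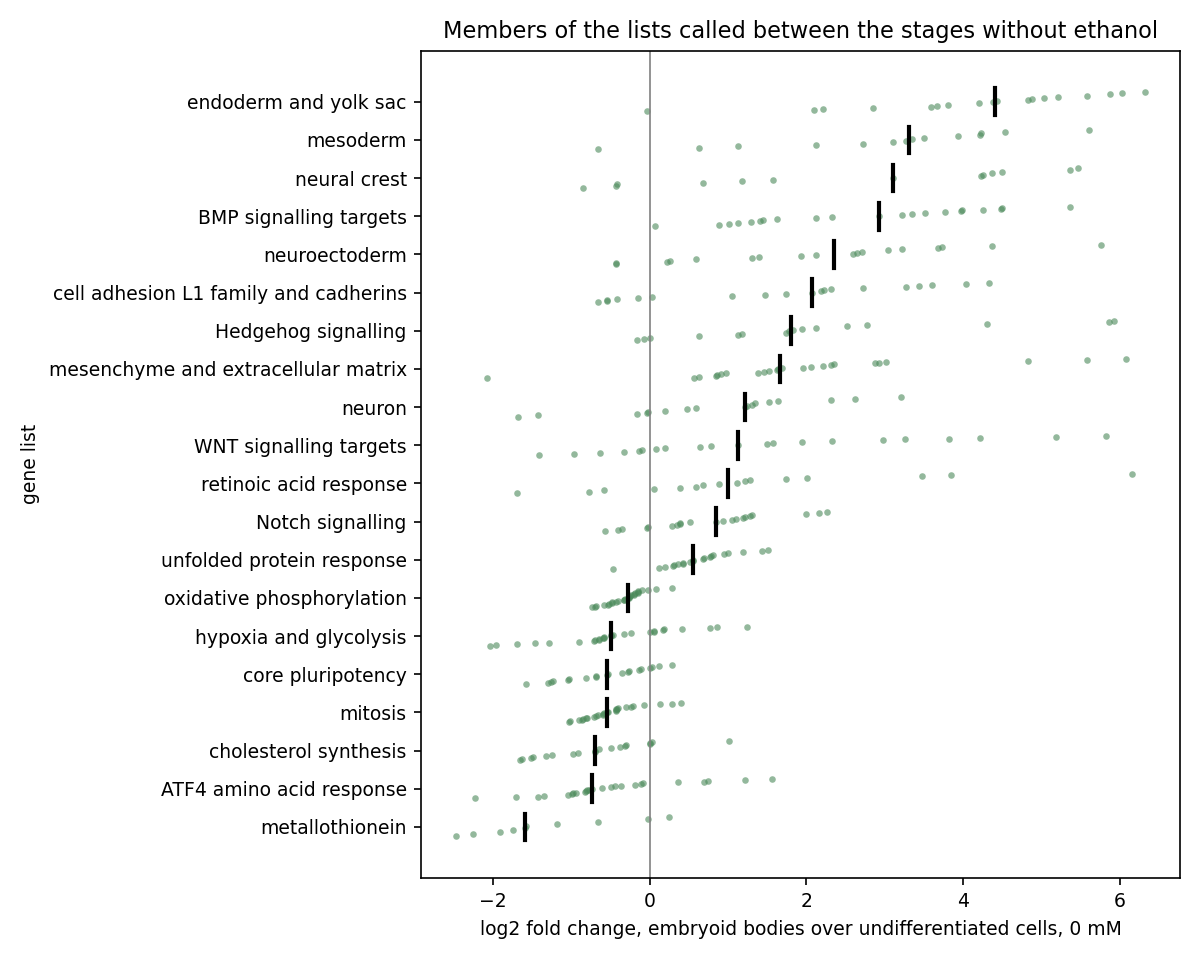
Each point is a tested member of a gene list (vertical axis) at its log2 fold change between embryoid bodies and undifferentiated cells without ethanol (horizontal axis), and black bars are list medians. Of the 20 lists called, 13 lie higher, up to a median of 4.41 for endoderm and yolk sac, and 7 lower, down to -1.59 for metallothioneins.

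Pluripotency, division and several metabolic lists were lower in embryoid bodies at 0 mM. Of 20 core pluripotency genes 14 fell and none rose (median -0.54, adjusted p = 0.000259; adjusted p = 0.17 with an estimated correlation), NANOG by 1.76-fold, ZFP42 by 2.4-fold and USP44 by 2.45-fold. Of 27 mitosis genes 19 fell, or 21 adjusted over the list alone (median -0.55, adjusted p = 1.36e-05; adjusted p = 0.155 with an estimated correlation), AURKA by 2.02-fold. Of 10 metallothionein genes 6 fell and 1 rose (median -1.59, adjusted p = 0.00199; adjusted p = 0.219 with an estimated correlation), MT1X by 5.56-fold. Of 19 cholesterol synthesis genes 14 fell and 1 rose (median -0.70, adjusted p = 0.000423; adjusted p = 0.401 with an estimated correlation), the regulator INSIG1 by 3.16-fold, while TM7SF2 rose 2.02-fold. Of 25 genes of the ATF4 amino acid response 16 fell and 5 rose (median -0.73, adjusted p = 0.0012; adjusted p = 0.203 with an estimated correlation), VLDLR by 4.68-fold and CTH by 2.69-fold, and PSPH fell 1.72-fold but was at 0.70 by its probe set with the highest SD. Of 27 hypoxia and glycolysis genes 16 fell, or 17 adjusted over the list alone, and 4 rose (median -0.50, adjusted p = 0.00292; adjusted p = 0.541 with an estimated correlation), HK2 by 3.24-fold. Of 28 oxidative phosphorylation genes 17 fell, or 18 adjusted over the list alone, and 1 rose (median -0.27, adjusted p = 0.000119; adjusted p = 0.25 with an estimated correlation). NDUFA1 fell 1.66-fold, and CYCS fell 1.60-fold but was at 0.93 by its probe set with the highest SD. Cyclic loess and the probe sets with the highest SD ended the oxidative phosphorylation call, and the latter also the hypoxia call. The metallothionein call ended without probe sets of the _x_at and _s_at kinds.

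With 20 mM ethanol in both stages, embryoid bodies differed from undifferentiated cells in 7922 genes, 4113 higher and 3809 lower. The plasma protein A2M rose 279-fold (log2 change 8.12 ± 0.34, n = 2 arrays per group, adjusted p = 4.57e-05), from a signal of 3.8 to 1060. The fibrinogen chains FGB and FGG rose 234- and 111-fold, and the matrix genes COL3A1 and LUM 123- and 119-fold. DLX2, SCN3A, ST18, MGP and NNAT rose 135- to 91.2-fold. Among these rises, all but COL3A1 and LUM started from undifferentiated signals under the array median, so their folds and ranks are imprecise, and A2M was at 17.8 in undifferentiated cells at 0 mM. Among the largest falls were cytidine deaminase (CDA, 25.4-fold), CHP2 (20.7-fold), KLK10 (16.0-fold), LINC02525 (15.3-fold), CGREF1 (13.2-fold), CXCL5 (12.6-fold), the complement gene C3 and C1orf94 (12.2-fold each), LINC00458 (11.6-fold, from 6380 to 550) and CDX4 (11.4-fold), of which all but CXCL5 and LINC00458 ended under the array median. A change of at least 2-fold was found for 1773 higher and 690 lower genes. At both doses, 6203 genes were called in the same direction and 16 in opposite directions, and fold changes across genes correlated by 0.911. Genes higher at both doses numbered 3360, against 1153 for independent calls. Median centring moved the median of all genes by -0.42 and gave 2268 higher and 6796 lower.

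At 20 mM 25 lists were called between the stages, 14 higher and 11 lower, among them the 20 called at 0 mM. With an estimated correlation 0 of the 25 were called, at adjusted p values of 0.145 to 0.586, as none was in any other contrast. The neuron call ended without either 0 mM undifferentiated array (24 lists each) and without the 20 mM embryoid body replicate B (25 lists). Of the others, imprinted genes were higher, with 12 of 17 rising and 3 falling (median 1.01, adjusted p = 0.0174; adjusted p = 0.145 with an estimated correlation), PLAGL1 by 25.1-fold and DLK1 by 5.56-fold. Of 17 heat shock genes 9 fell, or 10 adjusted over the list alone, and 1 rose (median -0.28, adjusted p = 0.0135; adjusted p = 0.145 with an estimated correlation), FKBP4 by 2.02-fold and HSPE1 by 1.84-fold. Of 25 S phase genes 15 fell and 2 rose, or 4 adjusted over the list alone (median -0.28, adjusted p = 0.0218; adjusted p = 0.145 with an estimated correlation), GINS1 by 1.76-fold, while UHRF1 rose 1.51-fold. RRM2 fell 1.24-fold, but was at 0.05 without probe sets of the _x_at and _s_at kinds. Of 25 housekeeping genes 13 fell and 3 rose (median -0.22, camera adjusted p = 0.0186, and adjusted p = 0.487 with an estimated correlation). HPRT1 fell 2.19-fold and GUSB rose 1.78-fold, and the list's median was 0.05 after cyclic loess. Of 25 ribosomal protein genes 8 fell, or 1 adjusted over the list alone (median -0.23, adjusted p = 0.00159; adjusted p = 0.586 with an estimated correlation), RPS9 by 1.41-fold. After cyclic loess the ribosomal median was 0.14, called higher (adjusted p = 0.0498), and the values of RPS15, RPL8 and RPS6 turned positive. Quantile normalisation ended the calls of heat shock, S phase, housekeeping and ribosomal protein genes. Cyclic loess ended those of heat shock (median -0.09), S phase (-0.06) and housekeeping genes. That these lists were called at 20 mM and not at 0 mM was tested by the difference of the ethanol effect between stages, where ribosomal proteins passed and the other lists did not. That pass was lost with quantile normalisation and with cyclic loess. It was also lost with an estimated correlation (adjusted p = 0.664), which called no list in any contrast.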

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

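The cyclic loess normalisation, the comparison of markers between lists, and the reading of the ribosomal percentile against the median of its random lists were chosen only after the results were seen. The effect of ethanol on 3 of 50 lists differed between the stages, by a camera test of the difference itself. The change in embryoid bodies minus that in undifferentiated cells had a median of -0.25 for ribosomal proteins, with 24 of 25 members negative (adjusted p = 0.000142; adjusted p = 0.664 with an estimated correlation), and RPS6 at -0.33. It was -0.20 for core pluripotency, with 18 of 20 negative (adjusted p = 0.00387; adjusted p = 0.664 with an estimated correlation), and USP44 at -0.48. It was 0.23 for mesenchyme and extracellular matrix, with 17 of 24 positive (adjusted p = 0.0102, and adjusted p = 0.664 with an estimated correlation), and POSTN at 0.75. The difference followed mean expression, from a median of 0.17 in the dimmest decile to -0.10 in the brightest. After cyclic loess camera no longer called ribosomal proteins (median -0.12, adjusted p = 0.16) or core pluripotency (-0.14, adjusted p = 0.1). Mesenchyme stayed called (0.31, adjusted p = 0.00128). Without cyclic loess, fry called 0 lists.

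Groups of abundant transcripts were lower with ethanol in embryoid bodies, for which a difference between arrays that grows with signal intensity was tested. Among 10000 random lists matched on mean expression, oxidative phosphorylation, housekeeping and heat shock genes lay at percentiles 3.18, 55.52 and 28.76, consistent with such a difference. Ribosomal proteins lay at 0.43, beyond the bound set beforehand against intensity, but that bound ignored size, as the random lists reached a median of -0.17 against -0.18, and NRF2 genes lay at 2.42 with a sampling interval of 2.13 to 2.74 around the limit of 2.5, so for these lists array intensity and a response of the genes cannot be told apart. Cyclic loess, which removes intensity trends, moved the ribosomal median from -0.18 (quartiles -0.22 and -0.15) to -0.03 (-0.09 and 0.01). It moved that of oxidative phosphorylation from -0.17 (-0.20 and -0.11) to -0.05 (-0.10 and 0.02) and that of NRF2 genes from -0.16 (-0.25 and 0.04) to -0.06 (-0.17 and 0.10). These calls ended with medians nearer 0, and why they ended was not tested. A response of these genes to ethanol stays open.

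Developmental lists moved with ethanol in embryoid bodies as well, and most moved further than random lists of like mean expression. That mean was taken over the arrays of both stages, so it need not match a list's signal in embryoid bodies alone. Mesenchyme and endoderm genes lay at percentile 100 of these, HOX genes at 99.96 and core pluripotency at 2.15 (sampling interval 1.87 to 2.45). These 4 were beyond the bounds set beforehand against intensity, while mesoderm genes lay at 96.72, within the central 95%. Random lists hold unrelated genes, whereas members of a real list can move together, so the percentiles may be too extreme. For mesenchyme the random median was -0.06 against 0.33, which argues against intensity as its whole cause. For endoderm the random median was 0.075 against 0.58, under the list's lower quartile of 0.14, and cyclic loess left a median of 0.52. These values argue against intensity as the whole cause for endoderm, although its call ended after cyclic loess. Random medians were 0.34 for HOX and -0.091 for core pluripotency, so the part of intensity in HOX and core pluripotency stays open. After cyclic loess mesenchyme stayed called, at 0.33 (quartiles -0.01 and 0.56) before and 0.37 (0.08 and 0.55) after. The estimated correlation was applied only without cyclic loess, where camera then did not call mesenchyme (adjusted p = 0.528). Core pluripotency went from -0.17 (-0.32 and -0.11) to -0.06 (-0.22 and -0.01) and HOX from 0.95 (0.49 and 1.17) to 0.66 (0.22 and 0.85). Both of these calls ended with smaller medians. Endoderm went from 0.58 (0.14 and 0.98) to 0.52 (0.05 and 0.85) and mesoderm from 0.34 (0.13 and 0.71) to 0.34 (-0.08 and 0.53), and their calls ended too; the cause was not tested.

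A lower share of undifferentiated cells in the ethanol-treated dishes could also move these lists, and was taken to raise the markers of every other cell type alike. The rise of a marker would also depend on its difference between the stages, whose medians ran from 1.21 for neuron to 4.41 for endoderm. Unequal rises are therefore no evidence against this explanation. Of the 6 germ layer and cell type lists among the 13 higher in embryoid bodies at 0 mM, 2 lay above the central 95% of the random lists and 0 below it. Medians of their markers were -0.05 for neuron, 0.07 for neural crest and 0.08 for neuroectoderm. They were 0.40 for mesenchyme, 0.50 for mesoderm and 0.53 for endoderm and yolk sac. The gap from lowest to highest was 0.58 (permutation p = 0.107, with a median gap of 0.41 in 10000 permutations). A changed share of undifferentiated cells and a change in particular cell types therefore cannot be told apart. Differences between dishes and an effect of ethanol on differentiation both stay open.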

How the results depend on the processing

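The cyclic loess normalisation was chosen after seeing the data. Of 3228 values of called genes under the alternatives, 2959 kept direction and call, 257 kept direction and lost the call, and 12 reversed, a total carried by the stage comparisons. For ethanol in embryoid bodies 71 of 213 such values kept the call, in undifferentiated cells 14 of 21, and on average 51 of 99. Of the uncalled values, 2152 stayed so, 121 were called in the same direction and 43 changed sign. Where a cause is not given, the cause was not tested.

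Reversed values came from the choice of probe sets or from cyclic loess. Without probe sets of the _x_at and _s_at kinds, ethanol changed DELE1 in embryoid bodies by -0.15, and the stage difference of RRM2 at 20 mM was 0.0498. At 0 mM, the probe set with the highest SD gave stage differences of 0.23 for RBFOX3, 0.70 for PSPH and 0.93 for CYCS, and the mean of all probe sets gave 0.16 for PSPH, 0.31 for CYCS and 0.38 for SDHD. At 20 mM that mean gave 0.0291 for RPS6, and cyclic loess gave 0.0246 for RPS15, 0.0874 for RPL8 and 0.0788 for RPS6.

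Without a filter, ethanol changed 2 genes in undifferentiated cells, 2 in embryoid bodies and 1 on average, 6 lists differed between stages, ethanol effects of the stages correlated by 0.084, and the correlation with the stage difference was 0.063 in embryoid bodies. The stricter filter gave 0, 473 and 10 genes, 13 genes and 5 lists that differed between stages, 1 list in undifferentiated cells and 6 in embryoid bodies, and correlations of 0.085 between stages and 0.20 and 0.34 with the stage difference. The mean of all probe sets gave 1 gene in embryoid bodies, 3 on average, 1, 4 and 1 lists in undifferentiated cells, in embryoid bodies and on average, and 0.13 between stages. Without probe sets of the _x_at and _s_at kinds there were 3 genes in undifferentiated cells, 0 in embryoid bodies, and 2, 0 and 2 lists in embryoid bodies, for the difference and on average. The probe set with the highest SD gave 4, 1 and 3 genes, 2, 1 and 1 lists for the same comparisons, 16 lists between stages at 20 mM, and 0.13 between stages.

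Quantile normalisation gave 62 genes and 5 lists in embryoid bodies, 1 list on average, and correlations of 0.089 between stages and 0.040 and 0.23 with the stage difference. Median centring, which shifts every gene of an array alike, gave 2, 4233 and 3997 genes in undifferentiated cells, in embryoid bodies and on average, 3 lists in undifferentiated cells and 9 for the difference. Cyclic loess gave 2 genes in undifferentiated cells, 2, 1 and 1 lists in embryoid bodies, for the difference and on average, 0.095 between stages and 0.13 with the stage difference in embryoid bodies.

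A trended and robust variance gave 0, 959, 31 and 17 genes in undifferentiated cells, in embryoid bodies, for the difference and on average, 2 lists in undifferentiated cells and 7 for the difference. A replicate block gave 0, 0 and 1 genes in undifferentiated cells, in embryoid bodies and on average, with 1 and 5 lists in undifferentiated cells and for the difference. Array weights gave 582 genes in embryoid bodies. With only the 4 arrays compared, limma called 0 genes for ethanol in either stage, with fewer degrees of freedom. An adjusted p under 0.10 gave 9, 541 and 50 genes. A log2 change of at least 1 gave 3 genes on average, and 2248 and 2463 between stages at 0 and 20 mM, by construction. The estimated correlation gave 0 lists in embryoid bodies, 0 for the difference, 0 on average and 0 between stages at either dose, and fry gave 0 for the difference, 0 on average, and 44 and 43 between stages.

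Leaving out 1 array at a time, with the lone array of its group assumed to vary like the other groups, gave 0 to 34 genes in undifferentiated cells, 0 to 4 in embryoid bodies, 0 to 10 for the difference, 0 to 18 on average, 5343 to 7671 between stages at 0 mM and 6081 to 7726 at 20 mM. Lists numbered 0 to 8, 6 to 9, 2 to 7, 3 to 11, 19 to 22 and 24 to 26 for these comparisons. Correlations were 0.10 to 0.15 between stages, and 0.021 to 0.18 and 0.13 to 0.21 with the stage difference in undifferentiated cells and embryoid bodies. Signals under the array median, as for MMP1 in undifferentiated cells at 2.99 and 12.6, limit how precisely a fold is known.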

Other observations

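The tests of the cell line were chosen only after the result was seen. In 4 of the 8 arrays, all of 1 stage, at least 3 of 4 checked transcripts that differ between cell lines did not match the line named in the labels. Arrays of that stage may hold another line, alone or mixed in, which cannot be told apart from the stage itself, since all 4 of its arrays were affected. All 8 labels name H9, so an exchange of the labels of the 2 stages could not by itself produce this mismatch. Such an exchange would also leave most core pluripotency genes higher in the arrays labelled embryoid body at 0 mM. Of these genes 15% were higher there, 3 of 20. Comparisons between stages, the difference of the ethanol effects and their average carry this doubt. Whether a share of another line differed between the dose groups of that stage was not tested. With only the 4 arrays compared limma called 0 genes in either stage, with 684 genes in undifferentiated cells and 3934 in embryoid bodies at an unadjusted p under 0.05.

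For the ethanol effect averaged over stages, the arrays can be divided within stages in 18 ways, too few for a share under 0.05. The real division called 5 genes and the highest of the others 5, with 2 divisions at that count, the real one included. That other division kept the embryoid body dose groups, with their direction reversed, and mixed doses in undifferentiated cells only. Divisions that mixed doses in both stages called at most 1 gene.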
